A study of Solanum lycopersicum with 17 samples.

How the data were processed

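RNA abundance was measured in tomato fruit with 17 Affymetrix tomato arrays. Per the labels, each array was hybridized with RNA from a pool of 8 fruits, extracted with a hot borate method and labelled with biotin by the one-cycle kit, and each array stands for 1 plant of its line. As far as the labels say, the replicates are therefore separate plants and pools. The deposited values are log2 RMA values (background-corrected, quantile-normalized and summarized per probe set by the authors with RMA, version not given), 1 per probe set and array. Scanner files were not used here. The log base was read from the range of the values.

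The table held 10209 probe sets. The 108 Affymetrix control probe sets (AFFX) were used only as checks, which left 10101 tested. The platform's probe annotation paired 909 of these with 1 gene (803 genes) and none with several genes, and 9192 had no gene name in the tables used here. Of the 909, 885 were matched by gene number to the RefSeq annotation of assembly SLM_r2.1, from which symbols and positions were taken, and 207 are known only by a LOC number.

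The arrays formed 6 groups by their labels, with 3 arrays each except 2 for DefH9-RolB. The comparisons, tests, gene lists, naming rule and first set of alternatives were fixed before the data were examined. One mean per group was fitted to each probe set with limma 3.58.1 in R 4.3.3 (lmFit and eBayes over all 17 arrays, 11 residual degrees of freedom and a prior of 2.56). Each comparison was a contrast of these means, and p-values were adjusted by Benjamini-Hochberg over the 10101 probe sets of that contrast, with a threshold of 0.05. The contrasts were the control without seeds and each of the 4 lines against the control with seeds, the mean of the 4 lines against each control, IaaM minus RolB, DefH9 minus INO, and the promoter by transgene interaction. A probe set changed the same way in all 4 lines when it passed in each with the same sign. Where a fit left 1 array in a group, that array was assumed to vary like those of the other groups.

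Named genes were taken by rule from probe sets with 1 gene that passed the threshold. For each group against the control with seeds, these were the 8 largest rises and 8 largest falls whose arrays did not overlap, and up to 3 members of each list by p. For each mean contrast they were the 6 largest in each direction, and for the change shared by the 4 lines the 10 with the largest smallest change. The report gives values mainly for those whose call held when any array was left out, and names the arrays behind the others. Genes outside the rule were chosen after their values were seen, and are named as such.

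The gene lists covered seed storage and late embryogenesis, auxin, ethylene, gibberellin, abscisic acid, cell wall modification, carotenoids and isoprenoids, photosynthesis, sucrose and starch, MADS-box factors, phenylpropanoids and flavonoids, cell cycle and histones, defence and proteinase inhibitors, heat shock proteins, and cuticle and lipid transfer. The first of these had no member among the named genes, so 14 were tested, with the probe set of highest mean for each gene. The test was limma's camera (preset correlation of 0.01) in the 5 contrasts against the control with seeds, 70 tests adjusted together. camera with an estimated correlation and fry were run beside it, and members were also counted when adjusted over the list alone. A further 11 lists, chosen after the annotation was read but before any value was compared, are given in the closing section.

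Replicate numbers were checked as possible pairs from the residual correlations of arrays with the same number. Only the 2 controls had all 3 of their pairs above 0.1 (0.164 to 0.478), so the controls may share plants, and a replicate block was run as an alternative: it called 397 probe sets between the controls in the full fit and 440 in a fit of the 6 control arrays, of which 267 were among the 437 of the fit without a block. The 2 controls alone without a block gave 239. Measures of single arrays were compared by exact two-sided permutation tests, 35 in all, adjusted together. Other alternatives were quantile normalization again, median centring, leaving out the lowest 30 percent of probe sets by mean, array weights, a trended and robust eBayes, stricter thresholds, a fit of the 2 groups alone, and leaving out each array. Covariates for RNA quality, for the gapdh signal and for the spike signal, and leaving out the 63 reporter probe sets, were added to these alternatives after seeing the data. On simulated data for INO-IaaM against the control with seeds, the fit called 29 of 67 probe sets changed by 0.5 on the log2 scale, 54 of 67 changed by 1 and 63 of 66 changed by 2, with 11 unchanged ones called. For DefH9-RolB the same counts were 11, 49 and 64, with 4 unchanged ones called. The analysis used R for the fits, Python 3.11.15 with pandas 2.3.3 for the annotation and matplotlib 3.10.9 for figures.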

Results

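Fruit of wild-type tomato was compared with fruit of 4 parthenocarpic transgenic lines, which set fruit without fertilization. The lines carried iaaM, a bacterial gene for auxin synthesis from tryptophan, or rolB, a bacterial gene that alters the response to auxin. Either was driven by the INO promoter (from the Arabidopsis ovule gene INNER NO OUTER) or by the DefH9 promoter (active in placenta and ovules). Wild-type fruit was hybridized to 6 arrays, 3 with its seeds and 3 after the seeds had been taken out by hand. Each line had 3 arrays, except that DefH9-RolB had 2. Array medians lay between 8.38 and 8.44, and the correlation of arrays within a group between 0.986 and 0.995. The number of arrays limits the precision of each value. Changes are differences of log2 values, with the standard error of the fit, and levels are means with SD.

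Several measures of the arrays themselves moved with the groups. The 5' minus 3' signal of the actin and gapdh control probe sets, a sign of RNA quality, averaged -0.46 ± 0.11 (SD, n = 11) in the lines, -0.74 ± 0.15 (SD, n = 3) in the control with seeds and -0.69 ± 0.19 (SD, n = 3) in the control without seeds. The lines exceeded the control with seeds by 0.28 (exact permutation p = 0.00549, adjusted p = 0.0214) and the control without seeds by 0.24 (exact permutation p = 0.0137, adjusted p = 0.0437). The difference of the hybridization spikes BioC and BioB was 1.09 ± 0.03 (SD, n = 5) in the RolB lines, 0.54 ± 0.05 (SD, n = 6) in the IaaM lines and 0.59 ± 0.09 (SD, n = 6) in the controls. The IaaM and RolB lines differed in it by -0.56 (exact permutation p = 0.00216, the smallest possible here, adjusted p = 0.0214). The 25S rRNA signal was higher in the lines than in the control with seeds by 1.28 (exact permutation p = 0.0192, adjusted p = 0.0481), and the gapdh 5' minus 3' signal differed between the IaaM and RolB lines by -0.10 (exact permutation p = 0.0173, adjusted p = 0.0466). The reporter probe set RPTR-Les-U57609-2_s_at lay between 7.14 and 11.31 in all 11 line arrays, against at most 4.09 in the 6 controls. RPTR-Les-A00196-1_s_at lay between 7.82 and 11.36 in 10 line arrays and at 3.93 in DefH9-RolB replicate 1, where the highest control was 4.36. The other 61 reporter probe sets lay between 2.45 and 5.49 on all arrays, so levels in that range are not told apart from absence. Differences that reach into it from above it are lower limits, and those between levels that both lie in it are not read as changes of a gene, although the counts include them.

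**Figure D1:**
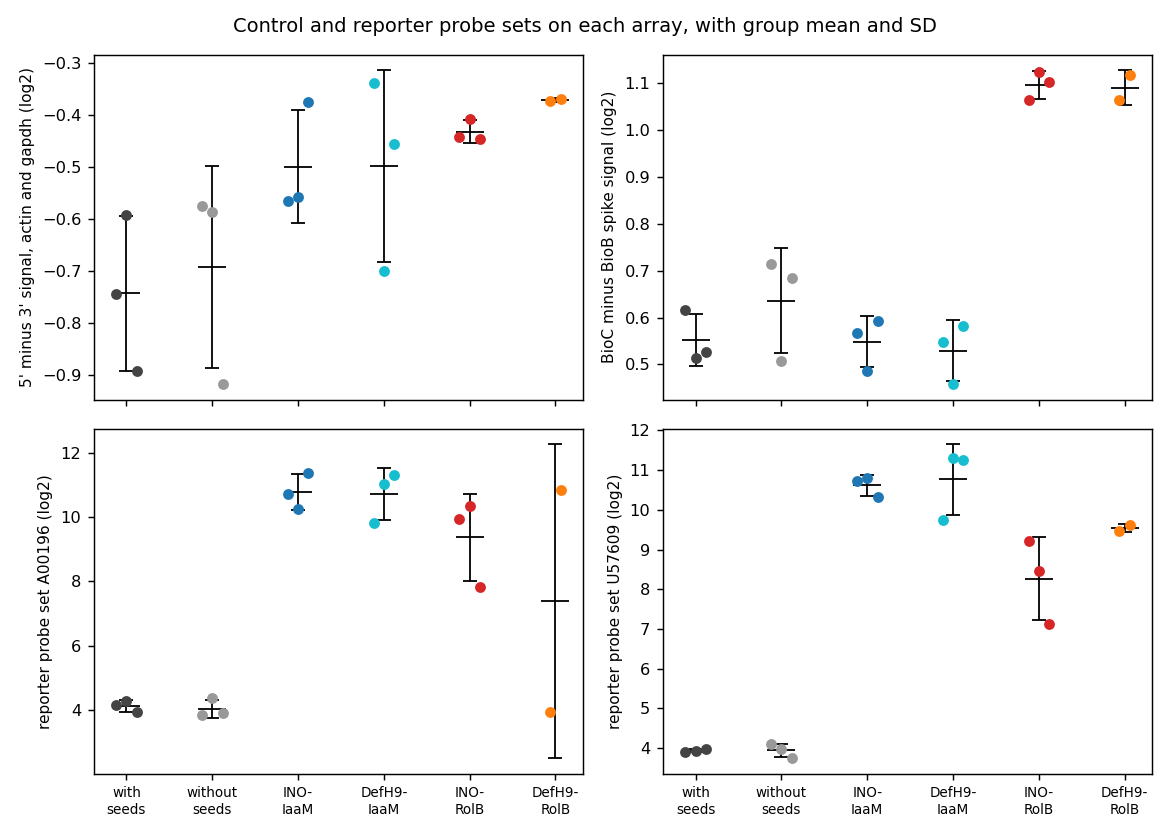
Control and reporter probe sets on each of the 17 arrays by group, in log2 units, with points for arrays and black marks for the group mean and SD. The BioC minus BioB difference lies between 1.06 and 1.12 on the RolB arrays and at most at 0.71 on all others, and the first reporter probe set is at 3.93 on DefH9-RolB replicate 1.

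The control without seeds was set against the control with seeds to find genes expressed in the seed. Fruit without seeds had far less transcript of CHS2 (chalcone synthase, the entry to flavonoid synthesis; chromosome 5, 66888326 to 66890029), which fell by 3.81 ± 0.63 (SE, adjusted p = 0.00277), from 11.58 ± 0.51 (SD, n = 3) to 7.77 ± 0.32 (SD, n = 3). GLB2, a haemoglobin gene, fell by 3.11 ± 0.32 (adjusted p = 6.68e-05), SNF4, a subunit of the SnRK1 energy-sensing kinase, fell by 2.85 ± 0.30 (adjusted p = 8.59e-05). THT1-3, a tyramine hydroxycinnamoyl transferase, fell by 2.51 ± 0.33 (adjusted p = 0.000497). The gene listed as gad2 fell by 4.10 ± 0.47 (adjusted p = 0.000164). Larger differences were seen for AGAL (alpha-galactosidase) at -6.00 ± 1.27 (adjusted p = 0.015) and GolS-1 (galactinol synthase, for raffinose-family sugars) at -5.04 ± 1.07 (adjusted p = 0.0155). Both levels varied between arrays without seeds, where AGAL averaged 5.59 ± 2.16 (SD, n = 3). AGAL lost its call without control without seeds replicate 1 or 2 or control with seeds replicate 3, and GolS-1 without control without seeds replicate 2 or control with seeds replicate 1 or 3, with adjusted p up to 0.0752 and 0.077.

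Genes that rose without seeds did so by less. Seed tissue had been taken out of these samples by hand, so a rise is a higher value in the tissue left. Whether expression in that tissue changed was not tested. IMP1, an inositol monophosphatase, rose by 1.07 ± 0.20 (SE, adjusted p = 0.00641), from 8.29 ± 0.11 to 9.36 ± 0.29 (SD, n = 3 each). MADS1 and TDR8, both MADS-box transcription factors, rose by 0.88 ± 0.15 (adjusted p = 0.0039) and 0.83 ± 0.13 (adjusted p = 0.00229). Among the 8 MADS-box genes, 2 rose and 6 did when adjusted over the list alone, and the list was higher by camera (adjusted p = 0.000118; adjusted p = 0.311 with an estimated correlation). Among 11 cell cycle and histone genes, CDKB2, a mitotic kinase, fell by 1.28 ± 0.20 (adjusted p = 0.0018). Of that list 3 fell when adjusted over the list alone, and it was lower by camera (adjusted p = 0.0137; adjusted p = 0.311 with an estimated correlation; 0.0715 without control with seeds replicate 3). Of 5 phenylpropanoid and flavonoid genes, 2 fell and 3 did when adjusted over the list alone, and the list was lower by camera (adjusted p = 0.0137; adjusted p = 0.311 with an estimated correlation). Of 7 auxin genes 1 was called lower, the Aux/IAA gene IAA2, and adjusted over the list alone 1 rose and 1 fell. IAA2 was at 3.75 ± 0.23 (SD, n = 3) with seeds and lower in every other group, all within the range of the silent reporter probe sets, so no change of it is read here or in the lines.

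In all, 334 probe sets were lower and 103 higher without seeds by limma, and 1584 had an unadjusted p under 0.05. The total of 437 came to 286 without control without seeds replicate 1, 258 without its replicate 2, and 224 without control with seeds replicate 3. The 334 came to 214 and 191 without the last 2 of these, and the 103 to 43, 44 and 33 without the 3 in turn.

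INO-IaaM was compared with the control with seeds. The seed-linked genes were low again: GolS-1 (chromosome 1, 86643986 to 86645371) fell by 6.22 ± 1.07 (SE, adjusted p = 0.00219), from 11.56 ± 0.48 to 5.34 ± 2.32 (SD, n = 3 each). AGAL fell by 6.27 ± 1.27 (adjusted p = 0.00579) and LOC544276, isocitrate lyase of the glyoxylate cycle, fell by 4.75 ± 0.63 (adjusted p = 0.000334). CHS2 fell by 4.11 ± 0.63 (adjusted p = 0.000967) and GLB2 fell by 4.01 ± 0.32 (adjusted p = 7.33e-06). Among the genes named by rule the largest measured rise was that of TPRP-F1, a proline-rich protein gene of young fruit (chromosome 7, 58640748 to 58642543), by 2.91 ± 0.56 (adjusted p = 0.00433), from 3.77 ± 0.32 to 6.68 ± 1.04. TPRP-F1 and MAN2 both start within the silent range, so their rises are lower limits and the rank is not settled. ER1, an ethylene-responsive proteinase inhibitor, rose by 2.69 ± 0.54 (adjusted p = 0.00559), P18, a dUTPase, by 1.69 ± 0.31 (adjusted p = 0.00317), and MAN2, an endo-mannanase, by 1.70 ± 0.38 (adjusted p = 0.00951).

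Among 25 ethylene genes in INO-IaaM, 3 rose and 5 fell (5 and 5 adjusted over the list alone). ACS3, an ACC synthase, fell by 3.43 ± 0.50 (SE, adjusted p = 0.000639) and EIL2, an EIN3-like factor, fell by 1.41 ± 0.21 (adjusted p = 0.00066), while CTR1, a kinase that represses ethylene signalling, rose by 0.71 ± 0.11 (adjusted p = 0.00109). Of 11 cell cycle genes, 3 rose and 3 fell, the same adjusted over the list alone: the replication clamp PCNA rose by 1.13 ± 0.19 (adjusted p = 0.0018), CDKB2 fell by 1.42 ± 0.20 (adjusted p = 0.00048), and CDKB1 is counted at levels within the silent range. Of 8 MADS-box genes 3 rose (3 adjusted over the list alone), among them MADS1 by 0.73 ± 0.15 (adjusted p = 0.00686), and the list gave a camera adjusted p of 0.0577. Of 12 defence genes 3 rose, among them NP24-I, an osmotin-like antifungal protein, by 1.56 ± 0.29 (adjusted p = 0.00313), and 4 rose and 1 fell adjusted over the list alone. Of 7 auxin genes 3 were called lower, also when adjusted over the list alone: IAA2, within the silent range, and the Aux/IAA genes IAA27 and IAA3, by -0.81 ± 0.23 (adjusted p = 0.0288) and -0.49 ± 0.14 (adjusted p = 0.0346). IAA27 lost its call without control with seeds replicate 1 or 3 or INO-IaaM replicate 1 or 2, and IAA3 without any array of either group, with adjusted p up to 0.104 and 0.115. IAA3 also lost it with the replicate block (adjusted p = 0.0526). In total 791 probe sets were lower and 832 higher, with 3192 at an unadjusted p under 0.05. The total of 1623 came to 927 without control with seeds replicate 1, 839 without its replicate 3, and 639 with the 5' minus 3' signal as a covariate.

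DefH9-IaaM, with the same transgene under the other promoter, was compared with the same control. AGAL fell by 7.80 ± 1.27 (SE, adjusted p = 0.00135) to 3.79 ± 0.97 (SD, n = 3), and GolS-1 fell by 7.54 ± 1.07 (adjusted p = 0.000528) to 4.02 ± 0.71 (SD, n = 3), both within the range of the silent reporter probe sets. The isocitrate lyase gene LOC544276 fell by 4.65 ± 0.63 (adjusted p = 0.00035), SNF4 fell by 3.86 ± 0.30 (adjusted p = 4.72e-06), and gad2 fell by 4.20 ± 0.47 (adjusted p = 6.94e-05). ER1 rose by 2.68 ± 0.54 (adjusted p = 0.00507) and NP24-I by 1.86 ± 0.29 (adjusted p = 0.000938). On arrays without seeds NP24-I lay at 11.56 to 11.87, above the 10.24 to 11.09 with seeds. The lowest array of the 4 lines, INO-IaaM replicate 2, was at 11.89. TBG7 and TBG1, beta-galactosidases of the cell wall, rose by 1.31 ± 0.27 (adjusted p = 0.00597) and 0.74 ± 0.13 (adjusted p = 0.00226), while TBG2 of the same family fell by 1.08 ± 0.11 (adjusted p = 3.01e-05). In all 2 of 28 cell wall genes rose and 1 fell, the same adjusted over the list alone.

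ACS3 and EIL2 fell in DefH9-IaaM as well, by 2.57 ± 0.50 (SE, adjusted p = 0.00392) and 1.37 ± 0.21 (adjusted p = 0.00078), and CTR1 rose by 0.75 ± 0.11 (adjusted p = 0.000719). In DefH9-IaaM 3 of 25 ethylene genes rose and 4 fell (4 and 4 adjusted over the list alone). Of 4 gibberellin genes the 1 called lower, also when adjusted over the list alone, was CPS, copalyl diphosphate synthase, at levels within the silent range. Of 8 MADS-box genes, MADS1, TDR4 and TDR8 rose, by 0.95 ± 0.15 (adjusted p = 0.00121), 0.49 ± 0.09 (adjusted p = 0.00281) and 0.67 ± 0.13 (adjusted p = 0.00435), the same 3 counted when adjusted over the list alone. That list was higher by camera (adjusted p = 0.0228; adjusted p = 0.577 with an estimated correlation), and its adjusted p was 0.0529 without control with seeds replicate 3, 0.0657 without DefH9-IaaM replicate 2 and 0.0539 without DefH9-IaaM replicate 3. Of 7 auxin genes 2 were called lower, the same adjusted over the list alone: IAA2, within the silent range, and IAA27 by -0.69 (adjusted p = 0.0490), a call lost without any of 11 arrays in turn (adjusted p up to 0.159). In total 822 probe sets were lower and 960 higher, with 3384 at an unadjusted p under 0.05. The total of 1782 came to 1031 and 999 without control with seeds replicates 1 and 3, 999 and 1074 without DefH9-IaaM replicates 1 and 3, and 881 with the 5' minus 3' signal as a covariate.

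INO-RolB was compared with the control with seeds in the same way. AGAL and GolS-1 fell by 7.02 ± 1.27 (SE, adjusted p = 0.00236) and 6.81 ± 1.07 (adjusted p = 0.000965). CHS2 fell by 4.81 ± 0.63 (adjusted p = 0.000233) to 6.77 ± 0.57 (SD, n = 3), and LOC544276 fell by 5.49 ± 0.63 (adjusted p = 8.5e-05). ODD, a 2-oxoglutarate-dependent dioxygenase, rose by 1.93 ± 0.42 (adjusted p = 0.00631), NP24-I rose by 1.97 ± 0.29 (adjusted p = 0.000572), and TPRP-F1 rose by 2.60 ± 0.56 (adjusted p = 0.00632). Of 7 auxin genes 2 were called lower, also when adjusted over the list alone. One was IAA2, within the silent range. The other, IAA3 (an Aux/IAA repressor of auxin signalling; chromosome 9, 60914843 to 60915587), fell by 1.13 ± 0.14 (adjusted p = 0.000199).

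Of 19 sucrose and starch genes 4 rose and 1 fell in INO-RolB (5 and 1 adjusted over the list alone). AgpL1, a large subunit of ADP-glucose pyrophosphorylase, was higher by 1.90 ± 0.51 (adjusted p = 0.0192; 0.0541 without control with seeds replicate 3), and by 1.11 without INO-RolB replicate 1. Smaller changes were those of sus3, a sucrose synthase, up by 0.57 ± 0.11 (SE, adjusted p = 0.00336) and SPS, sucrose-phosphate synthase, up by 0.29 ± 0.06 (adjusted p = 0.00608). Of 28 cell wall genes 3 rose and 3 fell, the same adjusted over the list alone, with the endoglucanase CEL8 down by -1.06 ± 0.24 (adjusted p = 0.00818) and TBG2 by -1.23 ± 0.11 (adjusted p = 1.28e-05). Of 8 MADS-box genes 4 rose and 5 did when adjusted over the list alone, among them MADS1 by 1.07 ± 0.15 (adjusted p = 0.00049) and TDR6 by 0.87 ± 0.14 (adjusted p = 0.00121), and the list was higher by camera (adjusted p = 0.0137; adjusted p = 0.577 with an estimated correlation). PCNA rose by 1.25 ± 0.19 (adjusted p = 0.000688), 1 of 3 cell cycle genes that rose where 1 fell, the same adjusted over the list alone. In total 978 probe sets were lower and 1200 higher, with 3543 at an unadjusted p under 0.05. The total of 2178 came to 1375 and 1310 without control with seeds replicates 1 and 3, 1188 without INO-RolB replicate 2, and 707 with the 5' minus 3' signal as a covariate.

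DefH9-RolB was compared with the control with seeds on 2 arrays against 3. TPRP-F1 rose by 3.35 ± 0.63 (SE, adjusted p = 0.00361) to 7.12 ± 0.09 (SD, n = 2), and cMDH, cytosolic malate dehydrogenase, rose by 3.06 ± 0.48 (adjusted p = 0.00114), from 6.77 ± 0.89 (SD, n = 3) to 9.83 ± 0.13 (SD, n = 2). LOC544276 fell by 4.57 ± 0.71 (adjusted p = 0.00107), SNF4 fell by 3.42 ± 0.34 (adjusted p = 6.52e-05) and ACS3 fell by 3.04 ± 0.56 (adjusted p = 0.00315). GolS-1 was lower by -5.96 ± 1.20 (adjusted p = 0.00539; 0.0781 without DefH9-RolB replicate 1), and CHS2 by -3.32 ± 0.70 (adjusted p = 0.00692; 0.0604 without DefH9-RolB replicate 2). AGAL was lower by -5.39 (adjusted p = 0.0210), a call lost without control with seeds replicate 1 or 3 or DefH9-RolB replicate 1 (adjusted p up to 0.174), and gad2 by -2.56 (adjusted p = 0.00590; 0.0527 without DefH9-RolB replicate 1). Of 7 auxin genes 2 were called lower, also when adjusted over the list alone: IAA2, within the silent range, and IAA3, which fell by 1.02 ± 0.16 (adjusted p = 0.0012). Another probe set of IAA16, not the one counted, was called higher (adjusted p = 0.0460, and 0.0692 with the replicate block) at levels within the silent range, and lost its call without any of 9 arrays in turn (adjusted p up to 0.167).

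Of 28 cell wall genes in DefH9-RolB, 4 rose and 4 fell, the same adjusted over the list alone, with TBG7 up by 1.74 ± 0.30 (SE, adjusted p = 0.00233) and CEL8 down by -1.32 ± 0.27 (adjusted p = 0.00584). NP24-I rose by 1.94 ± 0.32 (adjusted p = 0.00163) and the chitinase CHI14 fell from 10.85 ± 0.15 (SD, n = 3) to 9.36 ± 0.52 (SD, n = 2, adjusted p = 0.000923). Of 12 defence genes 2 rose and 2 fell, also when adjusted over the list alone. ETR5, an ethylene receptor, fell by 1.14 ± 0.18 (adjusted p = 0.00117), 1 of 4 ethylene genes that fell where 1 rose of 25 (4 and 2 adjusted over the list alone). Of 8 MADS-box genes 5 rose (5 adjusted over the list alone), among them TDR6 by 1.01 ± 0.16 (adjusted p = 0.00114), with a camera adjusted p of 0.0577 for the list. In total 734 probe sets were lower and 898 higher, with 3223 at an unadjusted p under 0.05. The total of 1632 came to 937 without control with seeds replicate 3, 660 and 810 without DefH9-RolB replicates 1 and 2, and 359 with the 5' minus 3' signal as a covariate.

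**Figure D2:**
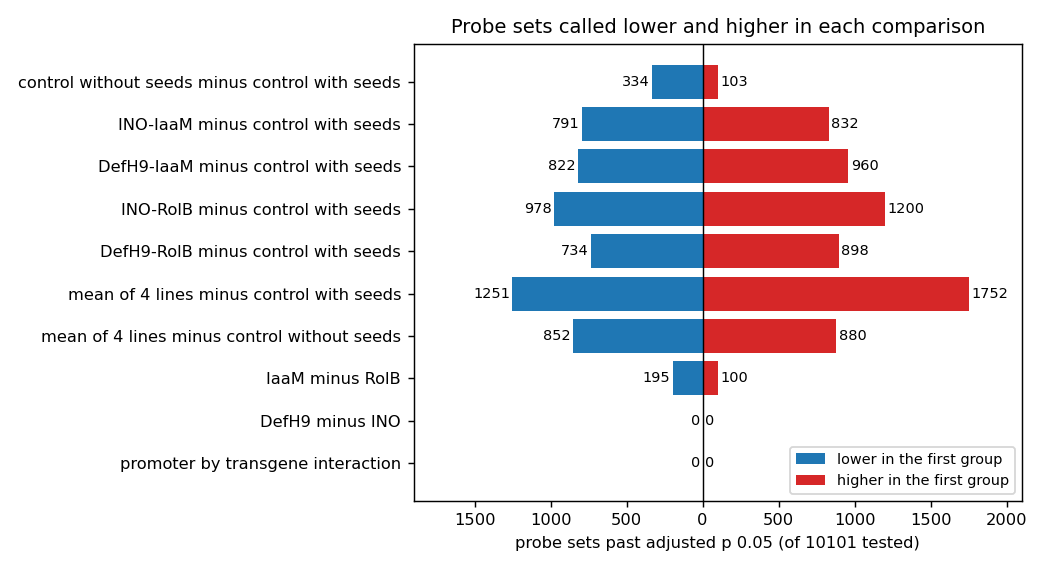
Number of probe sets past an adjusted p of 0.05 in each comparison, lower to the left and higher to the right of 0, of 10101 tested. The mean of the 4 lines against the control with seeds gives the most, 1251 lower and 1752 higher, and DefH9 minus INO and the interaction give 0.

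The 4 lines together were compared with the control with seeds for what parthenocarpic fruit shared. GolS-1 fell by 6.63 ± 0.86 (SE, adjusted p = 0.000138), from 11.56 ± 0.48 (SD, n = 3) to 4.86 ± 1.49 (SD, n = 11), and AGAL fell by 6.62 ± 1.02 (adjusted p = 0.000484). LOC544276 fell by 4.87 ± 0.51 (adjusted p = 2.04e-05) and CHS2 fell by 4.11 ± 0.50 (adjusted p = 8.75e-05). In the mean the lipid transfer gene TSW12 fell by 4.19 ± 1.03 (adjusted p = 0.00885), but passed in neither DefH9 line (adjusted p = 0.0955 with IaaM and 0.0914 with RolB). GluB (a beta-1,3-glucanase) rose by 2.83 ± 0.58 (adjusted p = 0.00295), ER1 by 2.65 ± 0.43 (adjusted p = 0.000721) and CHI9 (a chitinase) by 2.61 ± 0.56 (adjusted p = 0.00423). TPRP-F1 rose by 2.77 ± 0.45 (adjusted p = 0.000678). The 10 genes with the largest change shared by all 4 lines were GolS-1, AGAL, LOC544276, SNF4, CHS2, GluB, THT1-3, ACS3, gad2 and CHI9. In each single line GluB and CHI9 lost their call without control with seeds replicate 1 or 3. AGAL, GolS-1, CHS2 and gad2 depended on single arrays in DefH9-RolB, as given above. GluB and CHI9 also lost their call without 1 array of the line itself: replicate 1 of INO-IaaM, replicate 3 of DefH9-IaaM, replicate 3 of INO-RolB or replicate 1 of DefH9-RolB, and CHI9 in DefH9-RolB without INO-RolB replicate 1. The highest adjusted p was 0.248 for GluB and 0.333 for CHI9, both in DefH9-RolB without its replicate 1. With the replicate block CHI9 did not pass in DefH9-RolB (adjusted p = 0.0723), and so was not shared by all 4 lines. Against the control without seeds, neither passed in the mean of the lines (0.18 ± 0.58, adjusted p = 0.859 for GluB; 1.01 ± 0.56, adjusted p = 0.237 for CHI9).

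The mean contrast called 1251 probe sets lower and 1752 higher, with 4143 at an unadjusted p under 0.05, and 741 changed the same way in all 4 lines, 411 lower and 330 higher. The mean contrast's 3003 came to 1862 and 1723 without control with seeds replicates 1 and 3, and to 979 with the 5' minus 3' signal as a covariate. The excess of rises was not kept: 504 were lower and 475 higher with that covariate, and 329 and 145 with a fold change limit of 1. The single lines turned the same way, with 328 lower and 92 higher in INO-IaaM, 321 and 129 in DefH9-IaaM, 340 and 184 in INO-RolB and 238 and 220 in DefH9-RolB at that limit. With the covariate they gave 400 and 239, 476 and 405, 370 and 337, and 197 and 162. At a threshold of 0.01 INO-IaaM gave 391 and 217, DefH9-IaaM 408 and 275 and INO-RolB 460 and 427. Leaving out any array of either group turned the excess in INO-IaaM, and leaving out replicate 1 or 3 of either group turned it in DefH9-IaaM.

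The balance of the 411 and 330 did not hold either. It turned with the lowest 30 percent of probe sets left out (278 lower and 354 higher) and with array weights (607 and 638). It was 172 and 43 with a fold change limit of 1, and 133 and 57 with the covariate. The 741 came to 461 and 384 without those replicates, to 391 and 406 without DefH9-RolB replicates 1 and 2, and to 190 with the covariate. Without those 4 arrays in turn the 411 came to 299, 262, 239 and 254, and the 330 to 162, 122, 152 and 152.

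**Figure D3:**
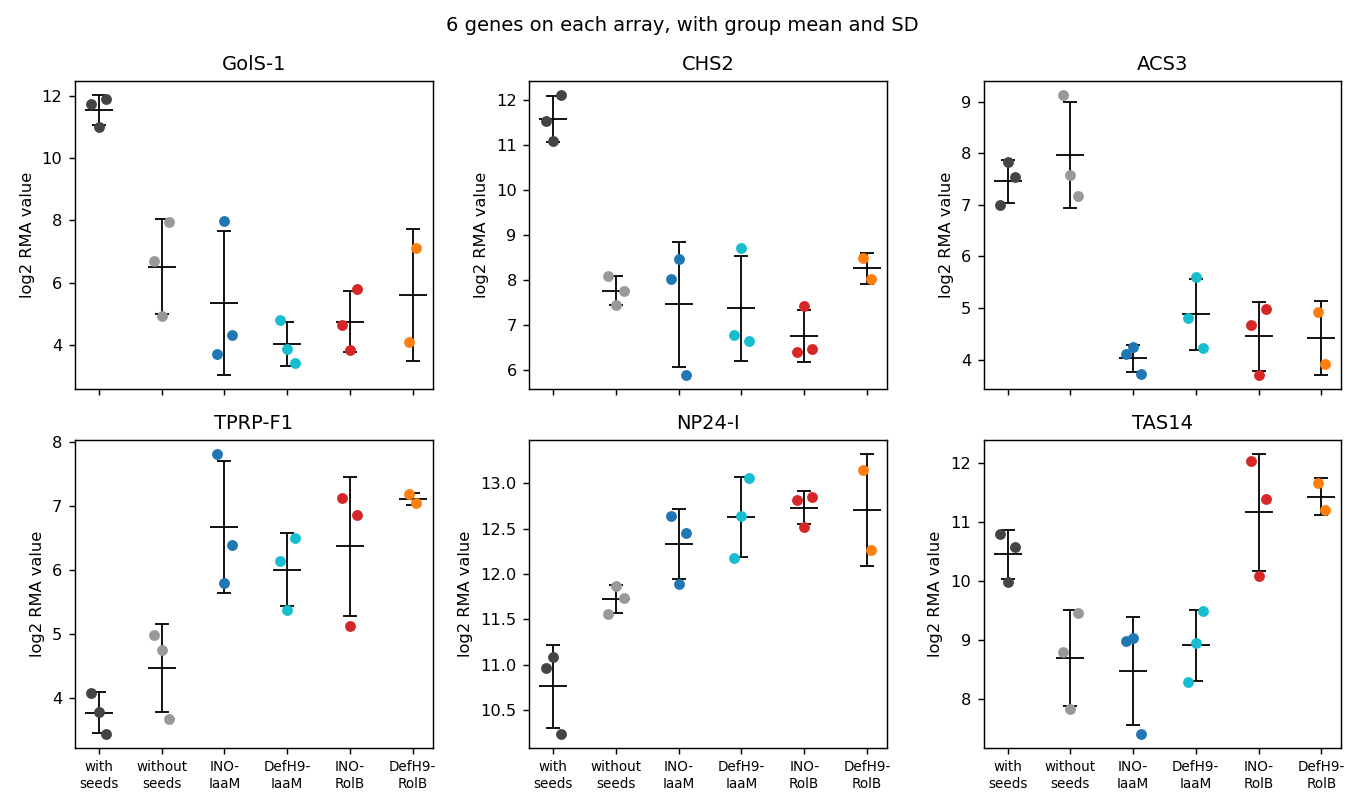
Log2 RMA values of 6 genes on each array by group, with points for arrays and black marks for the group mean and SD (n = 3, and n = 2 for DefH9-RolB). GolS-1 and CHS2 are low in all groups but the control with seeds, ACS3 is low in the lines alone, and TAS14 averages 8.69 in the IaaM lines and 11.28 in the RolB lines.

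Whether the lines resembled fruit without seeds was asked in 2 ways. Of the 334 probe sets that fell when seeds were removed, 215 (64.4%) also fell in all 4 lines and 296 (88.6%) in their mean, and 0 rose in the mean. These comparisons share the control with seeds, which alone gives fold changes a correlation: over all probe sets the correlation of seed removal with each line was 0.646 to 0.741, and 0.405 to 0.523 in simulations of unchanged groups with that control shared. The covariances were 0.172 to 0.206, against 0.0268 to 0.0308 simulated. The 215 of 334 came to 132 of 191 without control with seeds replicate 3 and to 139 of 320 without DefH9-RolB replicate 1, and the share lay between 43.4% and 76.2% when any array was left out. The 296 came to 195 without control without seeds replicate 2 and 178 without control with seeds replicate 3. Of the 103 that rose, 26 (25.2%) rose in all 4 lines and 64 (62.1%) in their mean, and 0 fell in the mean. The count of 26 came to 4 without control with seeds replicate 3, and to 8 and 12 without control without seeds replicates 2 and 1. It came to 12 and 14 without DefH9-RolB replicates 1 and 2, 17 and 15 without INO-IaaM replicates 1 and 3, and 17 without INO-RolB replicate 1. GolS-1 and CHS2 were 2 of the genes low in both, and in the mean of the lines they differed from the control without seeds by -1.59 ± 0.86 (SE, adjusted p = 0.223) and -0.30 ± 0.50 (adjusted p = 0.725), values that passed no threshold.

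Genes that set the lines apart from fruit without seeds included ACS3 (chromosome 2, 69521744 to 69523472), which fell by 3.52 ± 0.40 (SE, adjusted p = 0.000308), from 7.96 ± 1.03 (SD, n = 3) to 4.44 ± 0.60 (SD, n = 11). The cell wall invertase gene lin5 fell by 2.87 ± 0.62 (adjusted p = 0.00878). ER5, an ethylene-responsive gene of the late embryogenesis abundant type, fell by 2.82 ± 0.49 (adjusted p = 0.00325), and yfe37 fell by 2.30 ± 0.33 (adjusted p = 0.00107). TPSI1, a phosphate-starvation gene, was lower in the lines by -2.23 ± 0.36 (adjusted p = 0.00211), at 7.87 ± 0.58 (SD, n = 11). Its level was 8.16 ± 0.36 with seeds and 10.10 ± 0.67 without (SD, n = 3 each). The difference thus came mostly from its rise without seeds, by 1.94 ± 0.45 (SE, adjusted p = 0.0253). P18 rose by 1.81 ± 0.25 (adjusted p = 0.00091), from 6.31 ± 0.85 (SD, n = 3) to 8.09 ± 0.24 (SD, n = 11), and LOC543715 rose by 1.51 ± 0.26 (adjusted p = 0.00329). ACO5, an ACC oxidase, was higher by 2.39 ± 0.54 (adjusted p = 0.0105; 0.0585 without control without seeds replicate 3), and TPRP-F1 by 2.08 ± 0.45 (adjusted p = 0.00883; 0.0651 without that array). LOC544276 was lower by -2.37 ± 0.51 (adjusted p = 0.00828; 0.0569 without that array). In total 852 probe sets were lower and 880 higher, with 3198 at an unadjusted p under 0.05. The small excess of rises turned with the replicate block (786 lower and 777 higher), with quantile normalization again (845 and 814) and with median centring (886 and 793). It did so too without any of 9 arrays in turn. The 5' minus 3' signal moved with this contrast by 0.24, and the total of 1732 came to 396 with it as a covariate (242 lower and 154 higher; 164 and 61 with a fold change limit of 1), and to 807 and 743 without control without seeds replicates 1 and 3.

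The IaaM lines were compared with the RolB lines for the effect of the transgene, with 2 lines for each. The SE and adjusted p rest on the spread of arrays within lines. They do not measure how lines of the same transgene vary. TAS14, a dehydrin gene induced by drought and abscisic acid (chromosome 2, 64231292 to 64232255), was lower with IaaM by -2.62 ± 0.42 (SE, adjusted p = 0.00771), at 8.69 ± 0.74 (SD, n = 6) against 11.28 ± 0.73 (SD, n = 5), where the controls were at 10.46 with seeds and 8.70 without. IAA3 was higher with IaaM than with RolB by 0.69 ± 0.11 (adjusted p = 0.00737). Its level was 11.26 with seeds, 10.77 and 10.99 in INO-IaaM and DefH9-IaaM, and 10.14 and 10.24 in INO-RolB and DefH9-RolB. Another probe set of IAA3 was higher in DefH9-IaaM than in the control with seeds by 0.76 ± 0.25 (adjusted p = 0.0486, and 0.0620 with the replicate block). Its call was lost without any of 14 arrays in turn (adjusted p up to 0.145), and its difference was 0.46 without DefH9-IaaM replicate 2. CHI14, at 10.85 with seeds and below that in every line, differed by 0.86 ± 0.15 (adjusted p = 0.012). TDR6, chosen after its values were seen, was lower with IaaM by -0.68 ± 0.11 (adjusted p = 0.00737). GLB2 and LOX1.1, a lipoxygenase gene, were lower by -1.47 ± 0.24 (adjusted p = 0.0089) and -0.89 ± 0.16 (adjusted p = 0.0132), with adjusted p of 0.0508 and 0.0598 without DefH9-RolB replicate 1. GLB2 was at 4.98 and 4.83 in INO-IaaM and DefH9-IaaM, within the silent range, at 5.54 in INO-RolB and at 7.20 in DefH9-RolB. Its difference thus lies mostly with DefH9-RolB. In total 195 probe sets were lower and 100 higher with IaaM, with 1900 at an unadjusted p under 0.05. With a fold change limit of 1 they were 40 and 2. The BioC minus BioB difference splits the arrays the same way as the transgene, and its values in the IaaM and RolB lines do not overlap. With it as a covariate limma called 0, and the median SE of the 295 went from 0.116 to 0.479. With the gapdh 5' minus 3' signal as a covariate it called 175. The total of 295 came to 154 without INO-IaaM replicate 2, 190 and 173 without DefH9-IaaM replicates 1 and 3, 175 without INO-RolB replicate 2, and 79 without DefH9-RolB replicate 1 (64 lower and 15 higher).

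The promoters were compared across the transgenes, and the interaction tested whether the promoter mattered more with one transgene than with the other. For DefH9 minus INO, limma called 0 probe sets, with 378 at an unadjusted p under 0.05, and for the interaction it called 0, with 386 at an unadjusted p under 0.05. Without INO-IaaM replicate 2 each of the contrasts called 1, and without DefH9-RolB replicate 1 they called 2 and 5.

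The other fixed lists gave no camera call in these 5 contrasts. Their counts follow in the order seed removal, then the IaaM lines (INO first), then the RolB lines (INO first). Of the 12 carotenoid and isoprenoid genes 1, 0, 1, 0 and 0 rose and 0 fell (2, 0, 0, 0 and 0 adjusted over the list alone), counting the probe set of highest mean for each gene. Another probe set of Psy1, phytoene synthase, was higher in DefH9-IaaM (adjusted p = 0.0456) and INO-RolB (adjusted p = 0.0294), calls lost without any of 13 and 3 arrays in turn (adjusted p up to 0.169 and 0.123). The Psy1 probe set of highest mean did not pass (adjusted p = 0.452 and 0.952). Of the 3 cuticle and lipid transfer genes 1, 2, 1, 2 and 0 fell and 0 rose. Adjusted over the list alone 2 fell in each contrast and 1 rose in each DefH9 line. TSW12 lost its call without any of 9 arrays in turn for seed removal (adjusted p up to 0.159), without control with seeds replicate 1 or 3 or INO-IaaM replicate 1 or 3 in INO-IaaM (up to 0.0684), and without control with seeds replicate 1 or 3 or INO-RolB replicate 2 in INO-RolB (up to 0.0938). The call of ltpg1 was lost without the same 4 arrays in INO-IaaM (up to 0.0714), without control with seeds replicate 3 in DefH9-IaaM (0.0516), and without that array or INO-RolB replicate 2 in INO-RolB (up to 0.0523). Of the 4 gibberellin genes 0, 1, 1, 1 and 2 fell (1, 1, 1, 2 and 2 adjusted over the list alone, where 1 rose in INO-RolB).

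Of the 3 abscisic acid genes 0, 0, 0, 1 and 0 rose and 0, 1, 0, 0 and 0 fell (1, 0, 0, 1 and 0, and 1, 1, 1, 1 and 0, adjusted over the list alone). TAS14 was lower in INO-IaaM by -1.98 ± 0.56 (SE, adjusted p = 0.0289), a call lost without control with seeds replicates 1 or 3 or INO-IaaM replicate 3 (adjusted p up to 0.11). NCED1, an abscisic acid synthesis gene, was higher in INO-RolB by 0.40 ± 0.12 (adjusted p = 0.0365), a call lost without any control with seeds array or INO-RolB replicate 1 or 2 (adjusted p up to 0.158), and with the replicate block (adjusted p = 0.0563). In the control without seeds the list's median was 0.06, its mean -0.43 and its test direction up, and in DefH9-RolB they were -0.01, 0.22 and down. Both heat shock genes passed in none. Of the 5 photosynthesis genes 1 fell in INO-RolB (1 adjusted over the list alone), where the list had a camera adjusted p of 0.0577. For the 28 cell wall genes the median, mean and test differed in sign in each line. They were -0.02, 0.03 and down in INO-IaaM, -0.05, 0.10 and down in DefH9-IaaM, -0.04, 0.04 and down in INO-RolB, and 0.11, 0.23 and down in DefH9-RolB. Signs also differed for the auxin genes in DefH9-IaaM (median 0.01, mean -0.14, test down), INO-RolB (0.12, -0.18, down) and DefH9-RolB (0.05, 0.03, down), and for the ethylene genes in INO-IaaM (0.07, -0.16, down). They differed too for the carotenoid genes in DefH9-IaaM (0.07, 0.01, down), for the cell cycle genes in INO-RolB (-0.21, 0.03, down), for the sucrose genes in DefH9-IaaM (0.09, -0.05, down), and for the defence genes without seeds (0.04, 0.29, down).

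The remaining counts of the lists described above are these. Of 25 ethylene genes 1 rose and 2 fell without seeds, and 2 rose and 5 fell in INO-RolB, the same adjusted over the list alone. Of 11 cell cycle genes 2 rose and 2 fell in DefH9-IaaM (3 and 3 adjusted over the list alone), and 2 rose and 0 fell in DefH9-RolB, also over the list alone. Of 12 defence genes 0 passed without seeds, 4 rose and 1 fell in DefH9-IaaM (5 and 1 adjusted over the list alone), and 2 rose and 2 fell in INO-RolB (4 and 2). Of 28 cell wall genes 0 rose and 2 fell without seeds (0 and 3 adjusted over the list alone), and 2 rose and 2 fell in INO-IaaM (1 and 2). Of 19 sucrose and starch genes 0 passed without seeds, 3 rose in INO-IaaM, also over the list alone, 1 rose and 1 fell in DefH9-IaaM (0 and 0), and 3 rose and 1 fell in DefH9-RolB, also over the list alone. Of 5 phenylpropanoid and flavonoid genes 1, 1, 2 and 1 fell in the lines (3, 3, 3 and 1 adjusted over the list alone) and 0 rose.

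Over the 70 list tests, camera called 5, camera with an estimated correlation called 0 and fry called 12. The 5 came to 8 without control without seeds replicate 1, 12 and 3 without control with seeds replicates 2 and 3, and 8 without DefH9-IaaM replicate 1.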

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

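The tests of the splits, of the spike batch and of RNA quality below were set before their results were seen. That of RNA quality is the ratio of fold changes with and without the mean 5' minus 3' covariate. Counts of calls with that covariate, the covariates for the spike and gapdh signals, and the choice of TDR6 came only after the data were seen.

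The IaaM and RolB lines differ from the control with seeds by different amounts for 295 probe sets, by the test of the difference itself. Among them, IaaM minus RolB was 0.86 for CHI14, 0.69 for IAA3, 0.65 for LOC543515, 0.60 for LOC543604, 0.49 for LOC543561 and 0.49 for GAL83, a subunit of the SnRK1 kinase. It was -2.62 for TAS14, -1.87 for GP1, the beta subunit of polygalacturonase, -1.64 for AgpL1, a large subunit of ADP-glucose pyrophosphorylase, -1.47 for GLB2, -0.96 for LOC778302, -0.89 for LOX1.1 and -0.68 for TDR6. TAS14, CHI14, IAA3 and TDR6 kept their call when any array was left out. GLB2 and LOX1.1 lost it without DefH9-RolB replicate 1 alone (adjusted p = 0.0508 and 0.0598), and the others with several arrays: the highest adjusted p was 0.101 for LOC543515 (8 arrays, and 0.0610 with the replicate block), 0.137 for LOC543604 (4), 0.166 for LOC543561 (6), 0.156 for GAL83 (9), 0.156 for GP1 (6), 0.201 for AgpL1 (7) and 0.145 for LOC778302 (7).

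The transgene may account for these differences, but so may a hybridization batch, since the BioC spike separates all RolB arrays from all others. If a batch were the cause, the controls, which share the spike level of the IaaM arrays, would lie with them: the median of control without seeds minus RolB, divided by IaaM minus RolB, was 0.840 over the 295 (bootstrap limits 0.763 and 0.906), and 0.921 with the control with seeds (bootstrap limits 0.828 and 1.03), so the value a batch needs is there. The RolB arrays are in both terms, which pushes the ratio up to 0.556 for probe sets changed in no group, and the same values would arise if only the RolB lines changed these genes, so batch and transgene stay open. The spike as a covariate decides nothing, since its values in the IaaM and RolB lines do not overlap. With it 0 were called, the median SE went from 0.116 to 0.479, and the fold changes moved as well: their median ratio to those without it was 0.897 (quartiles 0.340 and 1.56), and 83.7% kept their sign. The mean 5' minus 3' signal as a covariate decides nothing about RNA quality, although the median ratio was 0.983 (quartiles 0.925 and 1.04), since that signal passed no threshold between the IaaM and RolB lines. The gapdh 5' minus 3' signal did differ, and is argued against as the whole cause: with it as a covariate the median ratio was 0.967 (quartiles 0.909 and 1.03) and all kept their sign. The calls kept were 139 of 295, with a median SE of 0.125 in place of 0.116, so a part in the count stays open. Noise in this signal would leave the ratio nearer 1, so RNA quality beyond what it measures stays open too. Of 100 splits of the 11 line arrays drawn from 462, 1 gave as many, the real one (295). The highest other gave 201 and moved only DefH9-IaaM replicate 2 and INO-RolB replicate 2 across. A chance assignment of single arrays can thus be excluded as the source of the count. Chance differences between whole lines cannot, since these splits moved single arrays. Splits that keep each line whole, by promoter and by the interaction, called 0, but are too few to decide.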

How the results depend on the processing

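As alternatives for the counts, the covariates and the fit without reporter probe sets were chosen after seeing the data. Quantile normalization again, median centring (largest shift of an array 0.0343), the trended and robust eBayes, and the fit without reporter probe sets kept each count within 1.5 times its value. So did the replicate block. With the lowest 30 percent of probe sets by mean left out (7070 remained), the seed comparison gave 244. Array weights gave 679 for seed removal, 2692, 2980 and 3320 for INO-IaaM, DefH9-IaaM and INO-RolB, 494 for IaaM minus RolB and 1245 for the change shared by all 4 lines. A fold change limit of 1 gave 189, 420, 450, 524 and 458 for seed removal and the 4 lines in that order, 474 and 225 for the mean of the lines against the controls with and without seeds, 42 for IaaM minus RolB and 215 for the shared change. A threshold of 0.01 gave 210, 608, 683, 887, 619, 1508, 560, 45 and 265 in the same order. A fit of the 2 groups alone gave 239 for seed removal, 711 for DefH9-IaaM and 808 for DefH9-RolB. The RNA quality covariate gave 639, 881, 707 and 359 for the lines, 979 and 396 for their mean against the controls with and without seeds, and 190 for the shared change. The spike covariate gave 0 and the gapdh covariate 175 for IaaM minus RolB. Estimated correlation gave 0 list calls and fry 12. Except where a stricter limit was set, the cause was not tested.

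Leaving out 1 array gave 224 to 463 for seed removal, 839 to 1852 for INO-IaaM, 999 to 2123 for DefH9-IaaM, 1188 to 2409 for INO-RolB, 660 to 1859 for DefH9-RolB, 1723 to 3241 and 743 to 2134 for the mean of the lines against the controls with and without seeds, 79 to 332 for IaaM minus RolB, 0 to 2 for DefH9 minus INO, 0 to 5 for the interaction, 384 to 894 for the shared change and 3 to 12 for list calls. Of 266 calls for named genes, 3 were lost with quantile normalization again, 5 with median centring, 17 with the replicate block and 99 without at least 1 array, and 0 reversed. Detection calls were not used here.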

Other observations

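The tests of the reporter probe sets and of the overlap between seed removal and the lines were chosen only after the results were seen. So were the genes of the next paragraph and the counts of calls with the covariate for RNA quality. The 11 lists were chosen after the annotation was read.

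Genes outside the fixed lists also differed in the lines. Against the control with seeds, the mean of the 4 lines was higher for MDHAR, the monodehydroascorbate reductase of ascorbate recycling, by 0.69 ± 0.13 (SE, adjusted p = 0.00189, n = 11 and 3), and for the glutathione peroxidase GPXle-2 by 0.35 ± 0.07 (adjusted p = 0.00242). It was higher for the succinyl-CoA ligase gene SCOA by 0.44 ± 0.07 (adjusted p = 0.000406), for the mitochondrial malate dehydrogenase mMDH1 by 0.40 ± 0.07 (adjusted p = 0.00115) and for TFT7, a 14-3-3 protein, by 0.54 ± 0.08 (adjusted p = 0.000605). ADC, the arginine decarboxylase of polyamine synthesis, fell by 0.43 ± 0.09 (adjusted p = 0.00294). SPE4 was lower by -1.79 ± 0.29 (adjusted p = 0.000695), at 3.74 ± 0.56 (SD, n = 11) against 5.51 ± 0.57 (SD, n = 3) with seeds. Nearly all of that difference lies within the silent range, so it is hardly read as a change of the gene. The expansin gene EXPA10 fell by 1.81 ± 0.25 (adjusted p = 0.000218) in the lines and by 2.50 ± 0.31 (adjusted p = 0.000289) without seeds. All of these calls held when any array was left out. The 5' minus 3' signal moved with the same contrast, by 0.28. SPE4 was also lower without seeds, by -1.87 ± 0.36 (SE, adjusted p = 0.00839).

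In the mean of the 4 lines against the control with seeds, 4 of 18 ascorbate and antioxidant genes rose and 0 fell, 3 of 19 amino acid, GABA and polyamine genes rose and 6 fell, 3 of 11 organic acid genes rose and 2 fell, 2 of 8 genes for 14-3-3 proteins rose and 0 fell, and 0 of 8 genes of the wider gibberellin list rose and 4 fell. There too 3 of 13 oxylipin genes rose and 4 fell, 2 of 11 ethylene response factors rose and 1 fell, 7 of 50 genes of the wider cell wall list rose and 8 fell, 0 of 9 of the wider auxin list rose and 3 fell, 0 of 12 of the wider photosynthesis list rose and 2 fell, and 0 of 9 of the wider heat shock list rose and 1 fell. Over the 55 tests of these 11 lists in the 5 contrasts against the control with seeds, camera called 0, camera with an estimated correlation 0 and fry 10. Adjusted over the list alone, the rises and falls in that mean were 4 and 2 for antioxidant genes, 4 and 9 for amino acid genes, 3 and 4 for organic acid genes, 2 and 0 for 14-3-3 genes and 0 and 4 for gibberellin genes. They were 3 and 4 for oxylipin genes, 2 and 2 for ethylene response factors, 9 and 8 for cell wall genes, 0 and 3 for auxin genes, 0 and 1 for photosynthesis genes and 0 and 1 for heat shock genes. Against the control without seeds the amino acid, GABA and polyamine list was lower by camera (adjusted p = 0.0204; adjusted p = 0.727 with an estimated correlation), with 6 members lower and 7 adjusted over the list alone. In IaaM minus RolB the wider heat shock list was lower by camera (adjusted p = 0.0171; adjusted p = 0.727 with an estimated correlation), with 0 members passing over all probe sets and 6 lower adjusted over the list alone.

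For the 1732 probe sets that separate the lines from the control without seeds, the transgenes are the explanation the design names, and it was not tested apart from line and plant. The measured 5' minus 3' signal is argued against as the whole cause. With it as a covariate the median ratio of the fold change to that without was 0.865 (quartiles 0.687 and 1.03), and all kept their sign. Of the 1732, 351 were still called, with a median SE of 0.137 in place of 0.117. The signal comes from actin and gapdh alone and its slope was fitted within groups, where noise in it would leave the ratio nearer 1. RNA quality beyond what this signal measures stays open. Handling while seeds were removed by hand may account for part of the differences. For the 852 that were lower in the lines, control without seeds minus control with seeds made up a median of 0.271 of the difference (quartiles 0.0379 and 0.558), which decides neither way. The control without seeds is in both terms, which pushes this ratio up, by an amount that was not computed. Of 100 splits of the 14 arrays drawn from 364, 1 gave as many, the real one (1732, against 1067 for the highest other). That other split kept control without seeds replicates 1 and 3 together and put DefH9-IaaM replicate 2 with them. A chance assignment of single arrays can thus be excluded as the source. The splits did not test chance differences between whole groups.

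The reporter probe set RPTR-Les-A00196-1_s_at is absent in DefH9-RolB replicate 1 alone among the line arrays. Wild-type fruit under that label is argued against, since the other reporter probe set lay 5.39 above the highest control array there. A swap with an array of another line stays open, but would not by itself account for the absence. All arrays of the other 3 lines carry the first reporter probe set, the lowest of them 3.46 above the highest control array. DefH9-RolB replicate 2 carries it too, at 10.83. Under any line label this array would thus be alone in lacking it. Its BioC minus BioB difference was 1.06, against at most 0.59 in the IaaM lines. A plant with only part of the construct, or of another transformation event, may be the source; neither was tested. The calls of DefH9-RolB against the control with seeds that were lost without this array do not single it out. Leaving out either DefH9-RolB array leaves 1 in the group and lowers that count. In IaaM minus RolB, however, no other array lowered the count as far when left out. GLB2 and LOX1.1 lost their call there without this array alone.

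Loss of the seed may account for part of what fell in the lines, and a part in what rose stays open. Of the probe sets lower without seeds, 64.4% (215 of 334) were lower in all 4 lines, and these make up 52.3% of the 411 lower in all 4 lines. The 215 came to 132 of 262 without control with seeds replicate 3 and to 139 of 239 and 166 of 254 without DefH9-RolB replicates 1 and 2. Rises overlapped as well: 64 of the 103 probe sets higher without seeds were higher in the mean of the lines, and 26 in all 4. Those 26 make up 7.88% of the 330 higher in all 4 lines. The shared control with seeds pushes the overlap of falls and that of rises up. Simulated unchanged groups hardly give any call, so their overlap decides nothing, and the share of the overlap due to the control stays open. Of the probe sets changed in all 4 lines, 50.1% (371 of 741) differed the same way from the control without seeds. Both comparisons use the same line arrays, which pushes this share up as well, and no value without that was computed, so it decides nothing about changes beyond the loss of seeds. The 371 came to 237 and 222 without control without seeds replicates 1 and 3, 202 and 203 without control with seeds replicates 1 and 3, and 218 and 194 without DefH9-RolB replicates 1 and 2, and the share to 31.2% without control without seeds replicate 3. The median of the 66 probe sets that fell by over 2 without seeds was 7.41 to 8.53 on arrays with seeds, 4.33 to 5.27 on arrays without, and 4.16 to 5.82 in the lines, with the highest line values on INO-IaaM replicate 2 (5.82) and DefH9-RolB replicate 2 (5.74). The 66 were chosen on the control arrays, so the gap between the controls was fixed by that choice. All values without seeds, and those of the lines but for these highest, lie within the silent range.

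The 6 arrays of seed removal and of each line with 3 arrays make only 10 splits, too few for a share under 0.05, and 1 split gave as many calls in each, the real one. DefH9-RolB was not split. The real and highest other counts were 437 and 0 for seed removal, 1623 and 1 for INO-IaaM, 1782 and 1 for DefH9-IaaM, and 2178 and 0 for INO-RolB. Of the 4 splits of the controls that part all 3 pairs of replicate numbers, the other 3 gave 0. For the mean of the 4 lines against the control with seeds, 1 of 100 splits gave as many (3003, against 33), and for the change shared by all 4 lines 1 of 100 (741, against 0). A chance assignment of single arrays can thus be excluded for both, while chance differences between whole groups were not tested. For DefH9 minus INO and for the interaction, 100 of 100 splits gave at least the real 0, which no split can miss, so the share decides nothing. The highest other counts were 20 and 158. The split with 158 set INO-RolB replicates 1 and 3 and both DefH9-RolB arrays, with DefH9-IaaM replicate 2, against the rest. It is the split that gave the highest other count for IaaM minus RolB. The split with 20 set INO-RolB replicates 2 and 3 and both DefH9-RolB arrays, with DefH9-IaaM replicate 1, against the rest. Both thus nearly follow the division into IaaM and RolB lines. For the list calls 37 of 100 permutations gave as many (5, against a highest of 16), so chance cannot be excluded.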
